A study of Rattus norvegicus with 28 samples.

How the data were processed

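The data were 28 RNA-seq libraries of Rattus norvegicus in 5 groups, given as a table of 18 brain libraries and a table of 10 libraries of sorted O4+ oligodendrocytes, each with 32623 genes. Per the labels' protocols, brain RNA was extracted with TRIzol, the sorted cells were processed with a SMART-seq low-input protocol in which cDNA is amplified before sequencing, and libraries were sequenced as paired-end reads on an Illumina NovaSeq instrument. Per the submitters' processing notes, cutadapt 1.9, FastQC 0.11.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and the genome build Rnor_6.0 were used. How gene counts were made from these tools, the annotation release and the strandedness are not given in the sources used here. Genes that share reads with a near-identical copy or overlap another gene are therefore uncertain.

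The values deposited by the authors are whole-number counts per gene, with totals that differ between libraries, and were used as deposited. Small counts pile up at multiples of 4. Of values from 1 to 40, 31.0% in brain and 33.4% in sorted cells are multiples of 4, where 25% would be even. How the counts were made was not tested, and the cause of the excess is open. Some genes are at exactly 0 in at least 1 library and reach 10 CPM or more in another. They make up 156 of the genes tested in brain and 477 of those tested in sorted cells.

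Groups and replicate numbers were taken from the sample titles. The labels give separate samples per group but do not say that each came from its own animal or litter, so p-values measure the spread between these samples. Litters are not given, although LPS was applied to dams. Pairs of libraries within a group were compared by a chi-square of their counts. The lowest value was 29.8 per degree of freedom, far above sampling noise, and no library was counted as a duplicate.

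Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), scaled by TMM, fitted by the quasi-likelihood method with group as the only term, and tested with Benjamini-Hochberg adjustment at 0.05. The 3 brain groups were fitted together and the sorted cells apart. Common biological coefficients of variation were 0.346 in brain and 0.650 in sorted cells. The standard error of a log2 fold change was taken from its F statistic. CPM (library-size-scaled counts) were taken from the TMM-scaled library sizes, and log2 CPM used a prior count of 2. The response of brain and sorted cells was compared by an interaction contrast with limma 3.58.1 (voomWithQualityWeights, a variance factor per table), over genes tested in both tables. Overlaps of comparisons that share controls were set beside splits of the controls and beside 50 simulations of unchanged groups, drawn around the mean of the real controls.

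These designs, the alternatives and 34 gene lists were fixed before the data were examined. The rule for named genes took, per comparison, the largest increases and decreases among genes with an adjusted p under 0.05, at least 5 CPM and a symbol, plus members of the lists and 6 marker genes, and where none pass, the 4 of smallest p. The files do not pair the Ensembl identifiers with names, and of the 47357 genes in the rat gene table used for names, 0 carry an Ensembl identifier. None of the gene list tests (33 lists), the marker genes, the removal of mitochondrial, globin and ribosomal protein genes, or checks of GC content and gene length could therefore be run. The rule was applied without the symbol, to 2 genes in each direction of brain LPS and hypoxia against control. The 4 genes of smallest p in the sorted cells, where none passed, are described without identifier.

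Alternatives were DESeq2 1.42.0, limma voomWithQualityWeights, RLE size factors, total-count scaling, no filter or a filter at 1 CPM, robust dispersions, a 2-fold threshold, unadjusted p, the replicate number as a block, 1 surrogate variable (sva 3.50.0), fits of only the groups compared, and each library left out in turn. Counts divided by 4, removal of genes at 0 in some libraries, and removal of libraries that stand apart were added after the data were seen.

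The edgeR, DESeq2 and limma tests were first run on simulated data, drawn from the real means, library sizes and dispersions with 200 genes changed by known folds. In brain LPS and hypoxia against control (17163 genes), edgeR recovered 32.8% of 1.5-fold, 59.7% of 2-fold and 80.3% of 4-fold changes, with 7 wrong calls among 122. In brain LPS against control (17163 genes) it recovered 40.3%, 68.7% and 89.4%, with 3 wrong calls among 135. In brain LPS and hypoxia against LPS (17163 genes) it recovered 37.3%, 59.7% and 81.8%, with 4 wrong calls among 123. In the same order of brain comparisons, DESeq2 made 33 wrong calls among 161, 27 among 173 and 32 among 167. There limma voomWithQualityWeights made 6 among 118, 1 among 129 and 4 among 122. In sorted cells (14637 genes) edgeR made 36 calls and none was wrong, DESeq2 made 48 wrong calls among 115, and limma voomWithQualityWeights made 1 among 33. The interaction test (14242 genes) recovered 49% of 4-fold and 68% of 8-fold differences, with 7 wrong calls among 124.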

Results

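Gene expression was measured in rats exposed to a perinatal dual-hit injury. Pregnant dams received lipopolysaccharide (LPS, a bacterial cell wall component that provokes inflammation) at 200 µg/kg by intraperitoneal injection on embryonic day 18.5. Offspring of the dual-hit groups were then kept at 8 ± 1% oxygen for 2.5 h per day, starting on postnatal day 3 and ending on postnatal day 11. Brain RNA was sequenced at postnatal day 11 in 6 control, 6 LPS and 6 LPS and hypoxia libraries. A separate cohort gave 5 control and 5 LPS and hypoxia libraries of oligodendrocytes sorted at postnatal day 9, before the last day of hypoxia, by the surface antigen O4, which marks late progenitors and immature oligodendrocytes. No group received hypoxia alone, so hypoxia was only measured on top of LPS. The labels describe the brain samples both as telencephalon and as whole brain.

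Total counts per library ran from 35779171 to 56966030 in brain controls, from 37788647 to 53103973 after LPS and from 27140316 to 53932877 after LPS and hypoxia. In sorted cells they ran from 39575219 to 48215466 in controls and from 36476103 to 43457329 after LPS and hypoxia. Brain libraries held counts for 18405 to 19540 genes. Sorted control replicate 2 held counts for 11956 genes, against 15876 to 16716 in the other sorted libraries, although its total of 44323038 lay within the range of the others. The first principal component, with 54.1% of the variance between sorted libraries, set this library apart. In brain the first component held 16.1% of the variance, and LPS replicates 6 and 3 lay farthest out on it, while LPS and hypoxia replicates 2 and 4 lay farthest out on the second. The genes are given as Ensembl identifiers with no symbol, so the text describes sets of genes by direction and size and names 4 identifiers, 2 that rose and 2 that fell in the dual-hit brain.

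**Figure D1:**
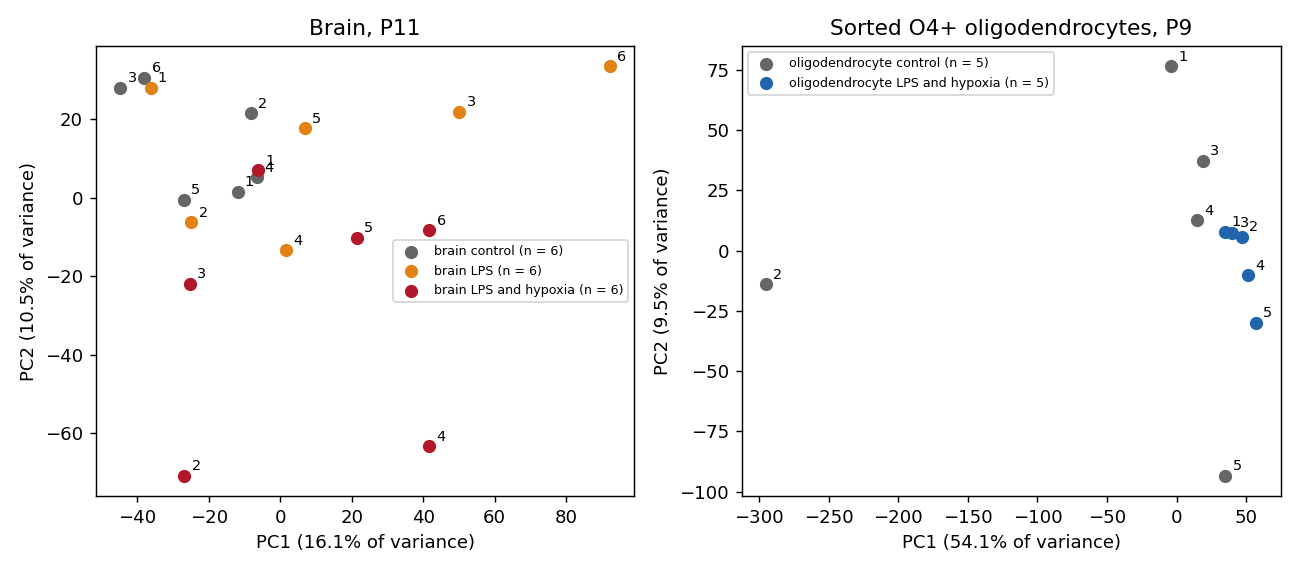
Principal components of log2 CPM in brain (left, 18 libraries) and sorted O4+ cells (right, 10 libraries); each point is a library, numbered by replicate and coloured by group, and axes are component scores with their share of variance. Sorted control replicate 2 lies apart from the other sorted libraries on the first component, and the brain groups overlap.

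Brain LPS and hypoxia against control asked what both hits together did to the postnatal brain. Of 17163 genes tested, 753 were higher and 814 lower after LPS and hypoxia, 9.13% of the genes tested. Most changes were small, with a median of 1.41-fold over the 1567 genes, and 91 genes rose and 106 fell by 2-fold or more. The 6 libraries of each group did not overlap for 818 of the 1567 genes. Over all tested genes 5.80% did not overlap, against 0.216% that chance gives for 6 against 6. The largest increase among genes of at least 5 CPM was that of ENSRNOG00000060289, at 13.3 ± 26.2 CPM (SD, n = 6) against 0.493 ± 0.266 CPM (SD, n = 6) in control, a log2 fold change of 4.74 ± 1.21 (SE, edgeR quasi-likelihood adjusted p = 0.0206). A single library carried most of it, LPS and hypoxia replicate 2 at 66.7 CPM with the others between 0.0677 and 5.23 CPM. Without that library its log2 fold change was 2.38 and the edgeR adjusted p was 0.103, within a range of 0.000243 to 0.504 over its alternatives, where limma voomWithQualityWeights gave the highest. ENSRNOG00000051482 rose from 1.06 ± 0.652 to 13.1 ± 10.4 CPM (SD, n = 6 each), a log2 fold change of 3.65 ± 0.92 (SE, edgeR adjusted p = 0.0191). It stood between 11.0 and 23.8 CPM in 4 of the 6 libraries and at 1.27 and 0.889 CPM in replicates 2 and 3, and its adjusted p was 0.118 with limma voomWithQualityWeights, the highest of a range from 0.000587. ENSRNOG00000015445 fell from 47.8 ± 37.6 to 4.98 ± 5.21 CPM (SD, n = 6 each), a log2 fold change of -3.25 ± 0.80 (SE, edgeR adjusted p = 0.0168). ENSRNOG00000022386 fell from 17.4 ± 8.88 to 2.26 ± 2.26 CPM (SD, n = 6 each), a log2 fold change of -2.93 ± 0.79 (SE, edgeR adjusted p = 0.0260). For none of the 4 were the groups fully separate. The call on ENSRNOG00000022386, whose adjusted p ran from 0.00576 to 0.0583 over its alternatives, was lost with edgeR adjusted p between 0.0520 and 0.0583 when control replicate 5 or 6 or LPS and hypoxia replicate 5 or 6 was left out. The number of genes called fell to 991 without LPS and hypoxia replicate 5, and was 996 without replicates 2 and 4, which lay apart on the second component. By limma voomWithQualityWeights it was 2784.

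**Figure D2:**
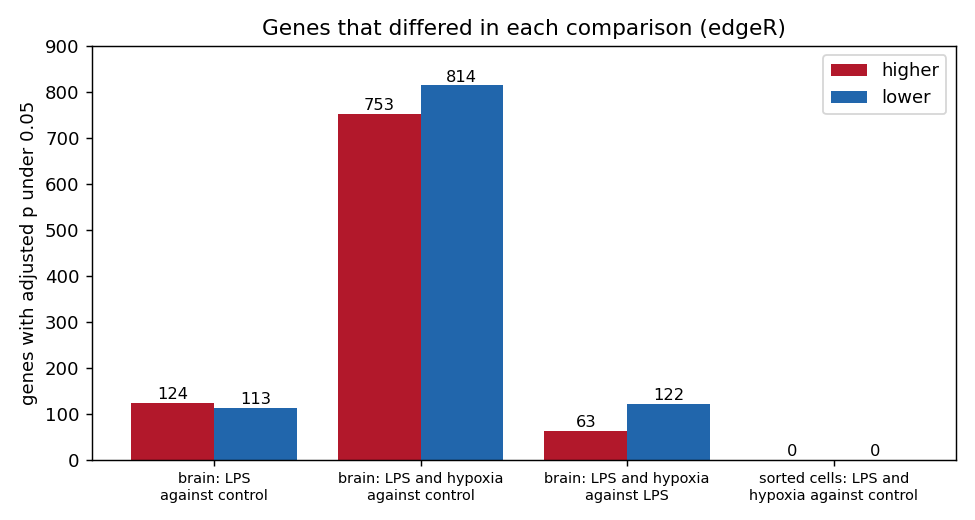
Number of genes with an edgeR quasi-likelihood adjusted p under 0.05 in each comparison (vertical axis, genes), higher in red and lower in blue. LPS and hypoxia against control gave 753 higher and 814 lower genes in brain, and no gene was called in sorted cells.

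**Figure D3:**
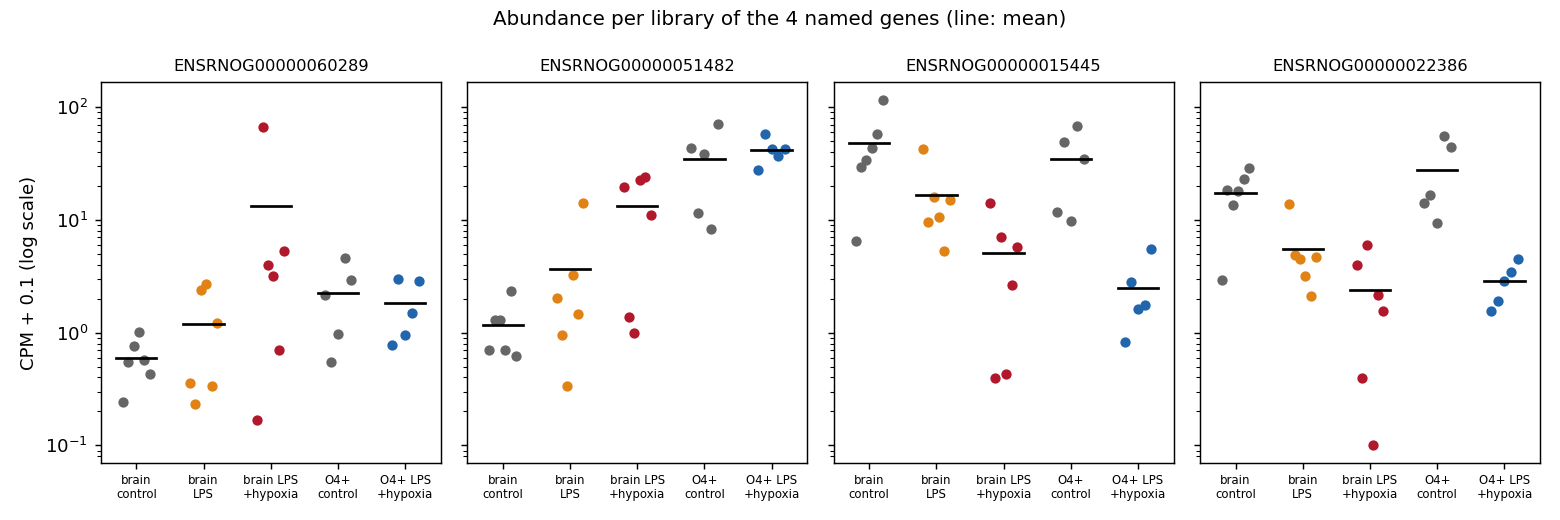
CPM plus 0.1 (log scale) of the 4 named genes in each library, by group. Each point is a library and the line is the group mean. ENSRNOG00000015445 and ENSRNOG00000022386 had lower means after LPS and hypoxia than in control in both brain and sorted cells, and the mean of ENSRNOG00000060289 after LPS and hypoxia in brain was set by 1 library at 66.7 CPM.

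Brain LPS against control measured the prenatal hit alone. After LPS 124 genes were higher and 113 lower, 1.38% of the 17163 genes tested. The median change was 1.48-fold over the 237 genes, with 22 genes up and 23 down by 2-fold or more. An unadjusted p under 0.05 was found for 3064 genes, against 858.2 expected by chance. None of the 4 named genes passed here. ENSRNOG00000015445 was at 16.4 ± 13.3 CPM and ENSRNOG00000022386 at 5.41 ± 4.20 CPM after LPS (SD, n = 6 each), between the control and dual-hit means, with log2 fold changes of -1.55 ± 0.75 and -1.68 ± 0.75 (SE) and edgeR adjusted p of 0.286 and 0.244. ENSRNOG00000051482 stood at 3.60 ± 5.21 CPM after LPS (SD, n = 6) and ENSRNOG00000060289 at 1.10 ± 1.09 CPM (SD, n = 6). The number of genes called depended strongly on single libraries. It was 24, 27 and 39 without control replicates 4, 5 and 6, and 34, 41, 44 and 91 without LPS replicates 3, 4, 5 and 6. It rose to 372 without control replicate 1 and to 738 without LPS replicate 1, and was 0 without LPS replicates 3 and 6 together. Scaled by total counts, 199 genes were higher and 105 lower, so the balance of directions depended on the scaling. The count was 36 in a fit of these groups alone, 1029 with DESeq2 and 619 with limma voomWithQualityWeights.

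The effects of LPS alone and of both hits ran in the same direction. All 172 genes called in both comparisons changed the same way, 87 higher and 85 lower, where independent lists of these sizes would share 5.44 and 5.36. Of the 1567 genes called after LPS and hypoxia, 94.1% had the same sign after LPS alone, and the median ratio of the LPS to the dual-hit log2 fold change was 0.547. Both comparisons use the same controls, which alone makes their fold changes correlate and can raise both values. Over the 1567 genes of smallest p in LPS and hypoxia against control, the median same-sign share was 51.1% and the median ratio 0.0149 in 50 simulations of unchanged groups. The simulations drew the treated libraries around the mean of the real controls, so they leave out the error of that mean. They therefore cannot show how much the shared controls alone add. With the controls split 3 and 3 they were 83.8% and 0.402 (medians of 20 splits, lowest 72.9% and 0.241). Across genes, which are not independent replicates, Pearson's r was 0.579 and the covariance 0.152. In those simulations, which leave out the error of the control mean, the median r was 0.0823 and the median covariance 0.00880. No gene was shared in them. With the controls split 3 and 3, so that no library served both comparisons, the median covariance over 20 splits was 0.113, with a range from 0.0831 to 0.138. The median number of shared genes was then 0 and the highest 87, since LPS against 3 controls called a median of 0 genes.

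**Figure D4:**
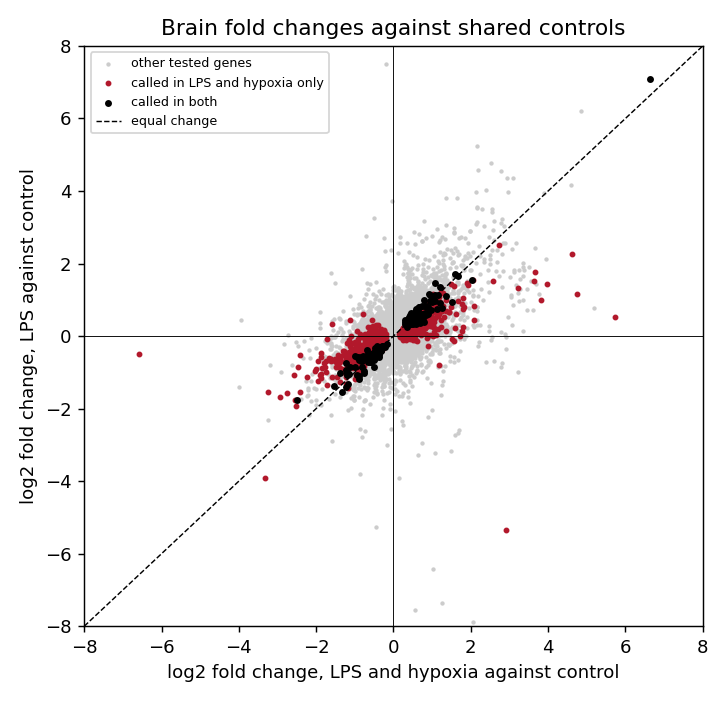
Log2 fold change against control after LPS (vertical) and after LPS and hypoxia (horizontal) for the 17163 brain genes; grey points are genes not called after LPS and hypoxia, red points are called there only, black points in both, and the dashed line marks equal change. All 172 black points lie in the quadrants where both changes have the same sign.

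Brain LPS and hypoxia against LPS measured what postnatal hypoxia added to the prenatal hit. More genes were lower than higher, 122 against 63, with a median change of 1.48-fold and 15 genes in each direction at 2-fold or more. Of these 185 genes, 108 were also called against control. All 108 changed the same way in both, which the LPS and hypoxia libraries shared by these comparisons favour, and this was not tested against chance. Of the 185, 14 had been called after LPS alone, 2 of them among the 108, and the other 12 moved in the opposite direction here. Only in this comparison were 65 genes called. Those 12 genes were not tested against chance, and the LPS libraries are shared by both comparisons, which favours opposite signs. None of the named genes passed, with ENSRNOG00000060289 nearest at a log2 fold change of 3.57 ± 1.14 (SE, edgeR adjusted p = 0.135, and 0.0202 with DESeq2). Without LPS and hypoxia replicate 2 its log2 fold change was 1.22 (edgeR adjusted p = 0.597), and with limma voomWithQualityWeights 0.783. Over that gene's alternatives in this comparison the adjusted p ran from 0.0202 to 0.819. The number of genes called was 117, 93, 77 and 105 without LPS replicates 1, 2, 3 and 6, and 63, 89 and 56 without LPS and hypoxia replicates 3, 4 and 5. It was 47 in a fit of these groups alone, 704 with DESeq2 and 486 with limma voomWithQualityWeights. Scaled by total counts, 55 genes were higher and 200 lower.

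**Figure D5:**
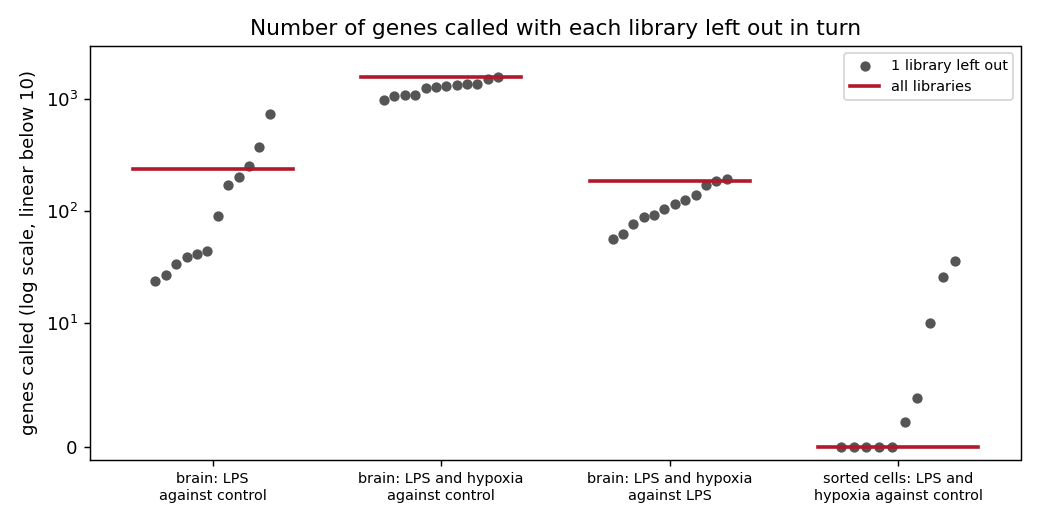
Number of genes called (vertical axis, log scale that is linear below 10) with each library left out in turn (grey points) and with all libraries (red lines) in the 4 comparisons. LPS against control in brain ranged from 24 to 738 genes, and LPS and hypoxia against control from 991 to 1585.

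Oligodendrocyte LPS and hypoxia against control asked how the dual hit altered the O4+ cells themselves. No gene of the 14637 tested passed with edgeR, where the smallest adjusted p was 0.0540. An unadjusted p under 0.05 was found for 1239 genes, against 731.9 expected by chance, with 490 higher and 749 lower. DESeq2 called 267 genes, 96 higher and 171 lower, and limma voomWithQualityWeights called 127, 72 higher and 55 lower. The 4 genes of smallest p were all lower after LPS and hypoxia, and for all 4 the groups did not overlap. The first was at 20.8 ± 4.44 CPM against 158.7 ± 91.5 CPM in control, 7.62-fold lower (SD, n = 5 each). The second, far more abundant, was at 347.0 ± 121.2 CPM against 2175 ± 849 CPM, 6.27-fold lower (SD, n = 5 each). The others were 8.37-fold and 4.61-fold lower, and all 4 had an edgeR adjusted p of 0.0540. Groups of 5 did not overlap for 491 genes, 3.35% of those tested, against 0.794% that chance gives. Of the 100 genes with the smallest p, 73 were lower. Both genes named as falling in brain were also lower here. ENSRNOG00000015445 was at 2.41 ± 1.83 CPM against 34.6 ± 24.99 CPM, a log2 fold change of -3.85 ± 0.67 (SE), and ENSRNOG00000022386 at 2.77 ± 1.20 CPM against 27.8 ± 20.5 CPM, a log2 fold change of -3.33 ± 0.54 (SE), with non-overlapping groups (SD, n = 5 each). Their edgeR adjusted p were 0.0625 and 0.0584, and over the alternatives they ran from 2.59e-07 to 0.374 and from 6.14e-09 to 0.374. ENSRNOG00000051482 was abundant in these cells at 41.3 ± 10.9 CPM against 34.5 ± 25.8 CPM in control (SD, n = 5 each), with an edgeR adjusted p of 0.923. With control replicates 1, 2, 3, 4 and 5 left out in turn, edgeR called 36, 10, 26, 2 and 4 genes, and none with any LPS and hypoxia library left out. Without the outlying control replicate 2, DESeq2 called 314 genes, 158 higher and 156 lower, so the lean of its calls to lower values depended on that library. By limma voomWithQualityWeights there were 94, 52 higher and 42 lower. In data simulated with the spread of these libraries, edgeR recovered 53.0% of 4-fold changes and 1.49% of 2-fold changes, so changes of the size most common in brain would mostly have gone undetected.

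The brain and sorted-cell effects of LPS and hypoxia were compared over 14242 genes tested in both. Across genes the log2 fold changes correlated weakly, with Pearson's r of 0.115 (jackknife SE 0.0660 over libraries) and Spearman's rho of 0.0849. Genes are not independent replicates, and over all 252 arrangements of the sorted libraries the exact one-sided permutation p of r, from differences of log2 CPM, was 0.0516. With DESeq2 fold changes r was 0.0455, and over the 6110 genes of at least 10 CPM in both tables it was 0.181. No overlap of calls could be formed, because edgeR called no gene in sorted cells. Of the 1467 brain genes called and tested in both, 55.1% had the same sign in sorted cells. An unadjusted p under 0.05 in sorted cells was found for 13.6% of these brain genes and for 7.98% of the other genes, an odds ratio of 1.82 (Fisher's exact test across genes, two-sided p = 7.27e-12). That p treats genes as independent and does not measure the spread between libraries. The excess was not tested over arrangements of the libraries, and genes were not matched for abundance. The response differed between brain and sorted cells for 64 genes by a test of the difference itself (limma voomWithQualityWeights, interaction). For 42 of them the log2 fold change was higher in sorted cells and for 22 it was lower. Opposite signs were found for 56 of the 64, and 29 had been called in brain. Choosing genes by the difference between the fold changes favours opposite signs, and the 56 were not tested against chance. None of the named genes differed, with adjusted p from 0.366 to 0.995. The count was 99 with edgeR and 111 over genes of at least 10 CPM in both tables. Age, library preparation and tissue differ together between the cohorts, so the 64 genes cannot be assigned to any of these.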

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

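The splits of the libraries, the pairs of LPS libraries taken out and the split of the controls were planned before their results were seen, while the tests on sorted control replicate 2, on steps of 4, with its simulations, and on the surrogate variable, the same-sign share and ratio under simulation and split controls, and the label of a count of 0 were chosen afterwards.

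Libraries far from the others of their group were found for 11 of 55 sets of values, at a nominal level of 1 in 20 per set. Several of the 11 are measures of the same library, and others are CPM of genes chosen for large changes. The nominal level is therefore not the chance rate of this count. Sorted control replicate 2 held counts for 11956 genes (others 15876 to 16336), had 12.1% of its counts in its top 10 genes (others 17.2% to 18.6%), a median correlation of 0.793 with other sorted libraries (others 0.890 to 0.917) and a mean log2 CPM of -0.57 over genes depleted in O4+ cells (others 1.24 to 1.62). Brain control replicate 6 had 2.98% of its counts in its top 10 genes (others 2.58% to 2.73%). Brain LPS replicate 6 had a median correlation of 0.930 with other brain libraries (others 0.951 to 0.956). Brain LPS and hypoxia replicate 2 had the lowest total count, 27140316 (others from 44266675). ENSRNOG00000060289 stood at 66.7 CPM in brain LPS and hypoxia replicate 2 (others up to 5.23), and ENSRNOG00000051482 at 14.04 CPM in brain LPS replicate 6 (others up to 3.17). In brain LPS replicate 1 ENSRNOG00000015445 stood at 42.4 CPM (others up to 15.9) and ENSRNOG00000022386 at 13.7 CPM (others up to 4.77).

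The response to LPS and hypoxia differed between brain and sorted oligodendrocytes for 64 genes by a test of the difference. Among 60 arrangements of the group labels within each table, 1 gave as many genes, the real one, and the highest of the others gave 1 gene. The arrangements also remove the brain response, so they stand for no response in either table and not for equal responses. They therefore cannot exclude chance for a difference between the responses. Without sorted control replicate 2 the test gave 54 genes.

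In brain, the real split gave more genes than every other of the 100 splits drawn in each comparison. LPS and hypoxia against control called 1567 genes and the highest other split 4, LPS against control 237 and 2, and LPS and hypoxia against LPS 185 and 4, with 1 split of 100 as large in each case, the real one. Chance can be excluded for these counts only as far as the libraries are independent samples. Litters are not given, so chance differences between litters were not tested.

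The first pattern is the dependence of the LPS calls on single libraries. Against 2 outlying LPS libraries, replicates 3 and 6, as the whole basis, 5 of the other 14 pairs also left 10 or fewer genes when taken out. Of these pairs only replicates 4 and 5 hold neither outlying library, and taking out any pair leaves fewer libraries to test. The count of pairs is thus weak evidence against that basis. With 1 surrogate variable in the fit, 76.4% of the 237 genes stayed called, so the variation it captured was not the basis of most calls. The variable was estimated with the groups in the model, so it could not test variation that follows the groups. That share also does not address the dependence on single libraries. Without replicates 3 and 6 the median log2 fold change of the 237 genes was 0.50, lowest of the 15 pairs, with the next at 0.52, against 0.57 with all libraries. Most pairs lowered the count. All 6 pairs among replicates 3, 4, 5 and 6 left 0, replicate 2 with 3, 4, 5 and 6 left 14, 130, 112 and 58, and replicates 1 and 3 left 216. Replicate 1 with 2, 4, 5 and 6 left 1146, 448, 426 and 318, where replicate 1 alone left 738. Why the pairs differ stays open. Unequal response between litters stays open, as untested, since litters are not given.

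The second pattern is the absence of edgeR calls in sorted cells beside an excess of small p-values. A count of 0 is reached by every split, 100 of 100, so splits cannot test it (the highest other split called 1 gene). At an unadjusted p under 0.05, 3 of 100 splits of the 10 libraries, the real one included, gave as many as the real 1239 genes, with 1336 the highest of the others. DESeq2's 267 genes were reached by 3 of 100 splits, with 356 the highest of the others. The 127 genes of limma voomWithQualityWeights were reached by 1 of 100, the real one, with 87 the highest of the others. Each share is under 0.05, the level set beforehand. The shares rest on the same 10 libraries and were not adjusted for one another, and other splits exceeded the first 2 counts. Chance is therefore made less likely but not excluded. In simulated counts for the sorted cells, 48 of DESeq2's 115 calls were wrong. Leaving out the low-complexity control replicate 2 gave 10 genes and leaving out control replicate 1 gave 36. These counts cannot decide whether replicate 2 hid calls, because the smallest adjusted p lay just over the threshold and small shifts add genes. In limma voomWithQualityWeights, which called 127 genes, its quality weight was 0.0674, against 0.616 to 2.31 in the other sorted libraries. Without replicate 2 that method called 94. Dividing the counts by 4 gave 30 genes, but in 16 of 20 simulations of sorted-cell counts without steps the division also added genes (at most 8), and the smallest adjusted p in the real counts, 0.0540, lay just over the threshold. Whether steps in the counts widen the fitted spread therefore cannot be told apart from an effect of the division, although 30 is above the simulated rises. Labelling the steps as fitting where the real rise exceeds every simulated one was the first rule, and it was replaced after the simulations were seen. A true group difference stays open.

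The third pattern is the shared direction of LPS alone and of both hits. Shared control libraries as its whole basis are argued against. With the controls split, so that no library served both comparisons, the covariance of the fold changes stayed at 0.113 (lowest split 0.0831). That median was 74.2% of the covariance with shared controls, and the lowest split 54.8%. The rule set beforehand used this share, and a comparison with the simulations of unchanged groups replaced it. Their highest covariance, 0.0169, is no bound on what shared controls add. The treated libraries were drawn there around the mean of those controls. A response to LPS common to both groups and any handling difference between controls and all treated animals cannot be separated by this design, in which every treated animal had LPS.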

How the results depend on the processing

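Counts divided by 4, removal of genes at 0 in some libraries and removal of libraries that stand apart were chosen after the data were seen. Causes of the shifts below were not tested, except where a stricter threshold set them by construction.

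Brain LPS against control, with 237 genes, gave 88 with no filter on low counts, 363 with counts divided by 4, 1029 with DESeq2, 619 with limma voomWithQualityWeights, 36 in a fit of its groups alone, 0 without LPS replicates 3 and 6, 45 with a 2-fold threshold, 403 with unadjusted p and 2-fold, and 24 to 738 with 1 library left out. Brain LPS and hypoxia against control, with 1567 genes, gave 2784 with limma voomWithQualityWeights, 996 without replicates 2 and 4, 197 with a 2-fold threshold, 480 with unadjusted p and 2-fold, and 991 to 1585 with 1 library left out. It stayed within 1.5 times under the remaining alternatives, where DESeq2 gave the highest count, 2340, close to that bound. In the simulated brain data DESeq2 made 27 to 33 wrong calls per comparison and edgeR 3 to 7, so DESeq2's larger brain counts call for caution. Brain LPS and hypoxia against LPS, with 185 genes, gave 103 with no filter, 310 with a surrogate variable, 704 with DESeq2, 486 with limma voomWithQualityWeights, 47 in a fit of its groups alone, 30 with a 2-fold threshold, and 56 to 193 with 1 library left out.

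Sorted cells, with 0 genes, gave 1 with total-count scaling, 9 with a surrogate variable, 30 with counts divided by 4, 22 without genes at 0 in some libraries, 267 with DESeq2 (96 higher, 171 lower) and 314 without control replicate 2 (158 higher, 156 lower), 127 with limma voomWithQualityWeights and 94 without control replicate 2, 423 with unadjusted p and 2-fold, and 0 to 36 with 1 library left out. The brain and sorted-cell correlation of 0.115 was 0.0455 with DESeq2 fold changes, 0.181 over genes of at least 10 CPM and 0.0712 to 0.137 with 1 library left out. The 64 genes that differed became 99 with edgeR and 111 over genes of at least 10 CPM. The 172 shared genes became 0 (median) with the controls split and 664 at an unadjusted p under 0.01.

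With the replicate number as a block, LPS against control gave 0 genes, LPS and hypoxia against control 1096, LPS and hypoxia against LPS 68, sorted cells 0, and the test of the difference 65. The numbers showed no consistent pairing of the samples. Deviations of same-numbered libraries correlated between -0.189 and 0.240, and at most 2 of 6 libraries correlated best with their own number. For brain control with LPS, the highest same-number correlation was 0.00526, against 0.241 between other numbers. It was above the others for brain control with LPS and hypoxia (0.237 against 0.190) and brain LPS with LPS and hypoxia (0.240 against 0.221). In sorted cells it was 0.113 against 0.0949. Pairing of some samples by number is therefore not excluded. The numbers mark no known litter, day or batch, so a call lost under the block is not read as a weaker effect, though fitted effects moved both ways.

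The 4 named genes kept their sign in 383 of 385 fits over all comparisons, and the exceptions were 2 genes far from the threshold in sorted cells. In brain LPS and hypoxia against control, ENSRNOG00000015445 passed in all 25 alternatives, ENSRNOG00000051482 in 23 of 25, ENSRNOG00000060289 in 21 of 25 and ENSRNOG00000022386 in 20 of 24. These genes were chosen for the largest called changes in that comparison, and the alternatives refit nearly the same libraries. Both tallies were thus favoured in advance and are no independent support. The gene list alternatives and the removal of mitochondrial, globin and ribosomal protein genes were not run, for want of gene symbols. Depth limits genes of few counts, where small counts also pile up at multiples of 4.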

Other observations

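The tests of O4+-enriched genes, of other brain cells and of the shared response were set before their results were seen, and the test on the pair of genes that fell was chosen after their values were seen. Both gene sets were themselves defined after the data were seen.

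By the mean of all libraries of each table, whatever their group, 570 genes of at least 5 CPM were 8-fold or more higher in O4+ cells than in brain and 3725 were 8-fold or more lower. Because the sets were chosen on these same libraries, the direction of the shares that follow was fixed by the choice, and they only describe the sets. The O4+-enriched genes took between 1.76% and 2.82% of counts in each brain library and between 32.3% and 51.0% in each sorted library. Genes depleted in O4+ cells took from 1.69% to 2.99% of counts in sorted libraries, against 40.7% to 45.9% in brain. Library preparation and age differ between the tables too, so these sets are not cell type markers alone.

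A lower level of O4+-enriched transcripts in the injured brain was not resolved. Their mean log2 CPM over 528 tested genes was 3.00 ± 0.21 in control brain, 2.91 ± 0.11 after LPS and 2.96 ± 0.06 after both hits (SD, n = 6 each). The differences from control were -0.09 (95% permutation interval -0.305 to 0.12) and -0.04 (-0.235 to 0.17), with exact two-sided permutation p of 0.353 and 0.634, and an adjusted p of 0.747 for both over 8 such tests. The intervals exclude a mean loss of more than 0.305 after LPS but include both 0 and smaller losses, so a p above 0.05, set beforehand as the bound against a loss, does not exclude one here. A preset-correlation set test (camera) gave p = 0.00581 after LPS and 0.0392 after both hits, and p = 0.425 and 0.547 with the correlation estimated from the data. Of the 528 genes, 13 were called higher and 34 lower after both hits, and 4 higher and 7 lower after LPS. Over all 17163 tested genes, 753 were higher and 814 lower after both hits, 9.13% of them. Calls in the set were thus about as frequent after both hits as over all genes. After LPS, 124 of all tested genes were higher and 113 lower.

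Transcripts depleted in O4+ cells had a mean log2 CPM of 1.63 ± 0.14 in sorted cells after LPS and hypoxia against 1.03 ± 0.90 in sorted controls (SD, n = 5 each, exact two-sided permutation p = 0.0556, adjusted p = 0.444). Without control replicate 2 the difference was 0.21, with an exact permutation p of 0.0952. As a share of counts, genes depleted in O4+ cells took 1.80% to 2.99% in sorted controls, with 2.47% in control replicate 2. After LPS and hypoxia they took 1.69% to 2.91%, so the groups overlapped. A difference in carried-over RNA of other brain cells is possible but was not shown.

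A shared response of brain and sorted cells was also not shown. From differences of log2 CPM, the same-sign share of the brain genes was 54.1%. It was as large in 47 of the 252 arrangements of the sorted libraries (exact one-sided permutation p = 0.187), with 59.9% the highest share among the others. Of the brain genes, 200 had an unadjusted edgeR p under 0.05 in sorted cells, and 129 of these had the same sign. That tally was not tested over the arrangements. With 5 libraries per group the test over arrangements does not exclude a partly shared response.

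The genes named as falling in the dual-hit brain varied together from library to library. The deviations of ENSRNOG00000015445 and ENSRNOG00000022386 from their group means correlated over the 18 brain libraries with Pearson's r of 0.916 and Spearman's rho of 0.886 (permutation p = 6.00e-05 and 9.00e-05 within groups, log2 of CPM plus 0.1), and with r of 0.907 without the 2 libraries farthest from the median. This is consistent with 1 source of variation acting on both genes, such as a difference between litters or reads shared between them. The files hold neither litters nor gene positions with which to tell these apart, and no other pair of genes was tested.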
